A study of Helianthus annuus with 32 samples.

How the data were processed

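RNA from aerial parts and roots of 2 inbred lines of sunflower (Helianthus annuus), grown with or without water stress, was measured on 32 one-colour Agilent arrays, 4 for each of 8 groups. Each array carried 42326 spots, of which 40909 held 40243 non-control probes of 60 bases, and was labelled with Cy3. The deposited scanner files give spot intensity on a linear scale, background-corrected by Agilent Feature Extraction, per the file headers. Version 10.10.1.1 is named in the headers of 12 arrays and version 11.5.1.1 in those of 20 arrays, while the submitters' processing notes name version 9.1. The 12 files of the earlier version hold all columns, and the 20 others lack the mean signal, so their median signal stood in for it where a mean was needed. Besides the scanner files, a value table of the series was deposited on a log2 scale, with 40243 rows that all matched a probe identifier. In all 32 columns the rank correlation with the median signal was highest for the column's own array, between 0.982 and 0.998. Against the processed signal it lay between 0.969 and 0.989. In the brighter part of each array the slope on the log2 median signal was 0.951 to 1.10, so the scale is log2, with higher values for brighter spots. Column medians lay between 7.30 and 7.34, and no percentile differed between columns by more than 0.294, so values were centred between arrays. The method of that centring is not given in the sources used here. This table served as an alternative.

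Values were log2 of the processed intensity minus each array's 75th percentile of it. Spots flagged as non-uniform or as population outliers were left out where another spot of the probe or another array of the group remained (239 probe values in all), and spots of 1 probe were averaged. A probe was tested if it was well above background on at least 3 of 4 arrays of at least 1 group, which kept 28792 of 40243 probes and left 11451 untested. Group means were fitted to all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), on 24 residual degrees of freedom per probe and 2.35 prior degrees of freedom. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe is called changed where the adjusted p is under 0.05. Errors of fold changes are moderated standard errors. All levels below are log2 values relative to the 75th percentile of the array, and a level of 1 probe is never set against that of another. The number of arrays, and the background for dim probes, limit the precision. Saturation was rare, at no more than 3 spots on any array.

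For a comparison of 1 group with another where a named probe was not well above background on any array of the dimmer group, only a bound on the fold is given. For line by stress no bound was computed, so the fitted difference is given and the text says where a group had no array well above background. The bound is the mean of the brighter group over the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal. It leaves out the error of the brighter group's mean, so "at least" refers to detection and is not a confidence limit. The labels number the arrays of each group 1 to 4 but do not say whether they come from separate plants or pools, so p-values measure the spread between these arrays, which may be partly technical. Arrays lay on 8 slides of 4, scanned on 3 days, with 12, 12 and 8 arrays per day. No slide held more than 1 array of a group, and each held arrays of at least 4 groups.

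The comparisons were fixed before the data were examined. They were stress against control in each line and tissue, the difference of that response between lines (line by stress, B71 minus B59), the line difference in each tissue and treatment, and the difference between root and aerial part in controls. Probes are named by a rule fixed at the same time. With no table pairing probes with genes, these were the 2 probes in each direction with the largest fold change among those past the threshold, well above background on all 4 arrays of the higher group, not saturated on every array of either group, and, outside the line-by-stress comparisons, with no overlap between the groups' values. For line by stress the higher group was the one with the highest mean. A set of 41 gene lists had also been fixed. The files give 40169 probes a custom identifier and 74 an EST accession, and none of these occurred among the 83308 genes of the RefSeq table supplied, so the lists and their alternatives could not be tested and no gene is named. Short protein motifs were also searched in the probe sequences, first with a small list and then, after its hits had been counted, with a longer one. No result from that search is used. Sets of tissue-preferred probes were added after the data were examined. A probe was aerial- or root-preferred if it differed between the control tissues past the threshold and at least 2-fold, and each set was defined in the other line, so that it shares no arrays with the comparison it was used in. A score is the mean of a set minus the mean of all other tested probes.

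The fit was tested on simulated data with the spread of each real probe pooled over the 8 groups and 200 of 28792 probes changed. In a simulated B59 aerial stress comparison it recovered 13.4% of probes changed by 0.5 on the log2 scale, 56.7% of those changed by 1 and 97.0% of those changed by 2, and 4.31% of its calls were false. In a simulated aerial line-by-stress comparison the shares were 1.49%, 47.8% and 72.7%, with 4.71% of calls false. In a simulated root line-by-stress comparison they were 2.99%, 28.4% and 68.2%, with 1.49% of calls false. The median standard error of the real values was 0.29 (log2) in both of these comparisons. Of all 11 simulated comparisons the line difference in control roots had the highest share of false calls, 7.76%, followed by the line difference in control aerial parts with 5.60%. Simulated noise was normal, without slide or scan-day effects, so these shares do not test groups of unequal spread. Median SDs of the real groups ran from 0.189 to 0.317 (log2). The 200 changed probes were far fewer than the 3235 to 8582 called under stress. Each recovery share rests on 66 or 67 probes, so the gap between aerial and root line by stress is imprecise. Alternatives were quantile normalization, the median over tested probes as the reference, normexp background correction of the raw signal (offset 50) followed by quantile normalization, the deposited log2 table, other filters on dim probes, flagged spots kept, only the compared groups in the fit, slide as a fixed or a random block, scan day or replicate number as a block, another variance model, array weights, and each array left out in turn.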

Results

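Sunflower line B59 is labelled sensitive and line B71 tolerant to water stress. Control plants received 50% Hoagland nutrient solution, and stressed plants received 400 mM mannitol, a solute that lowers the water potential around the root, at -0.989 MPa. Tissue was taken at 20 days. Whether the mannitol was dissolved in nutrient solution is not stated in the labels, so nutrient supply may have differed between the groups. Each line, tissue and treatment had 4 arrays. The 75th percentile of the processed signal ranged from 517 to 2804 between arrays, and 61.7% to 70.8% of spots were well above background.

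**Figure D1:**
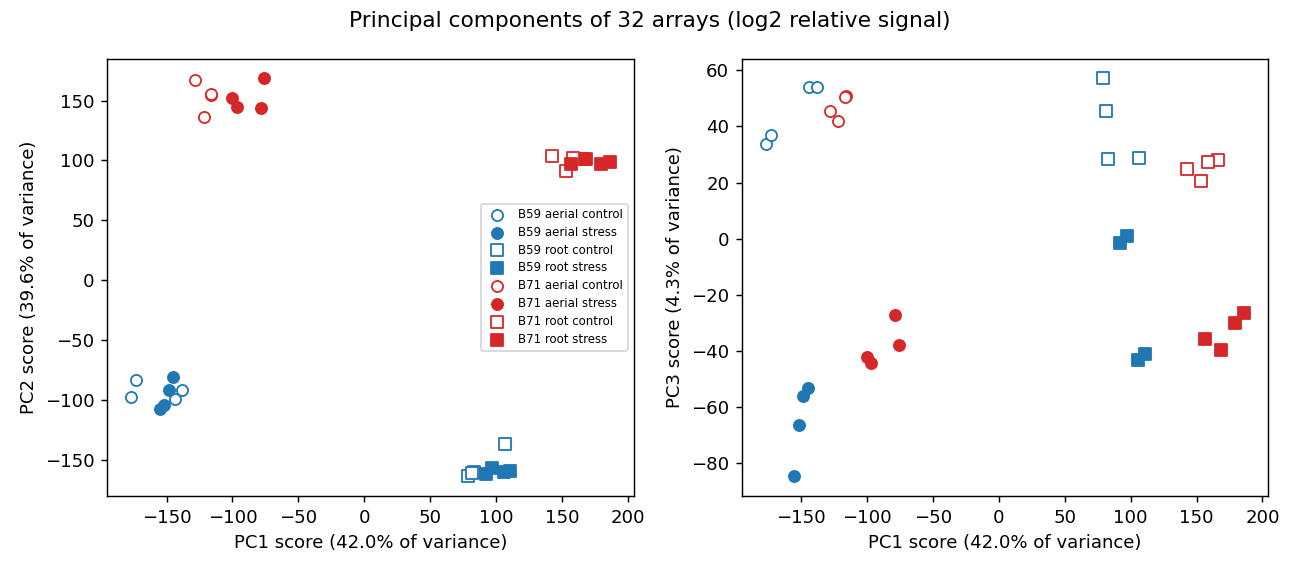
Scores of the 32 arrays on the first 3 principal components of log2 relative signal (left, PC1 against PC2; right, PC1 against PC3), with circles for aerial parts, squares for roots, blue for B59, red for B71, open symbols for controls and filled symbols for stress. PC1 (42.0% of variance) separates the tissues, PC2 (39.6%) the lines, and PC3 (4.31%) ranks stressed arrays below the controls of their line and tissue.

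In the control plants 19230 of 28792 probes differed between root and aerial part, averaged over both lines. Signals were higher in the root for 12181 probes and lower for 7049. Among the differences of at least 2-fold, 3720 probes were higher in the root and 4227 in the aerial part. The median difference over all tested probes was 0.21 (log2), and it was 0.18 with the array median as the reference and 0.27 after quantile normalization, so the excess of higher calls is relative to the reference of each array. Without a filter on dim probes 49.1% of the calls were higher in the root, against 63.3% with it.

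Water stress changed 8582 probes in the aerial part of B59, 4100 upwards and 4482 downwards. Of these, 2995 changed at least 2-fold. Probe CUST_12826_PI423492394 (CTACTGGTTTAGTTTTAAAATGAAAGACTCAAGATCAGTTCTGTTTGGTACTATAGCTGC) rose from -5.68 ± 0.62 in controls to 0.51 ± 0.12 under stress (SD, n = 4), a log2 fold change of 6.18 ± 0.33 (SE, limma adjusted p = 1.53e-12), although only 2 of the 4 control arrays were well above background. CUST_14393_PI423492394 rose by 5.92 ± 0.71 (SE), again with 2 control arrays above background. Probe CUST_35586_PI423492394 (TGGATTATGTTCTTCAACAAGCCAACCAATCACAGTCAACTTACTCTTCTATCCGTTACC) was at -0.29 ± 1.22 (SD, n = 4) in controls and not well above background on any stressed array, which is at least 70.2-fold lower (limma adjusted p = 2.6e-09). CUST_39432_PI423492394 was at least 36.7-fold lower under stress. The count was 4916 when only the 8 arrays of this comparison entered the fit. On slide 1, which held 1 array of each group, 86.5% of 7869 probes called from the other arrays moved in the same direction. With slide as a fixed block 7696 probes passed.

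In the aerial part of B71 6229 probes changed, 3009 upwards and 3220 downwards, 2090 of them at least 2-fold. CUST_14252_PI423492394 (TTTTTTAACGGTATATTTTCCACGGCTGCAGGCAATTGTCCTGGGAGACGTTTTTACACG) was not well above background in any control array and at -1.01 ± 0.86 (SD, n = 4) under stress, at least 38.3-fold higher (limma adjusted p = 3.46e-12). CUST_14251_PI423492394 rose by 6.83 ± 0.38 (SE), from -5.24 ± 0.77 to 1.59 ± 0.56 (SD, n = 4). Both of these probes also rose in the root of B71, by 3.36 and 3.25, and in both tissues of B59, by 2.96 to 3.84. Downwards, CUST_6910_PI423492394 changed by -8.76 ± 1.03 (SE), from 3.20 ± 0.81 to -5.56 ± 2.14 (SD, n = 4), and CUST_8301_PI423492394 by -8.63 ± 1.02 (SE), with 3 and 1 stressed arrays above background. Slide 3 held 1 array of each group, and 93.2% of 4963 probes called from the other arrays moved the same way there. With slide as a fixed block 4485 probes passed, and with array weights 10805.

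In the root of B59 stress changed 3235 probes, 1774 upwards and 1461 downwards, 1281 of them at least 2-fold. CUST_27512_PI423492394 (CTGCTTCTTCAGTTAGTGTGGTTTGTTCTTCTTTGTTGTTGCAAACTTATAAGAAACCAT) rose from -6.12 ± 0.38 to 0.99 ± 0.78 (SD, n = 4), by 7.11 ± 0.43 on the log2 scale (SE, limma adjusted p = 7.3e-11). In the root of B71 it rose by 3.63, and in the aerial part it was not called in either line. CUST_7570_PI423492394 was not well above background in any control array and at least 44.2-fold higher under stress. CUST_29664_PI423492394 changed by -4.56 ± 0.73 (SE), from -1.38 ± 1.78 to -5.93 ± 1.74 (SD, n = 4). CUST_32352_PI423492394 changed by -4.49 ± 0.77 (SE), from -0.70 ± 2.00 to -5.19 ± 1.66 (SD, n = 4). Each had 2 stressed arrays above background. Their SEs draw on the spread of all 8 groups, while the spread in the compared groups was wide. This count rested on few arrays. It was 1534 without B59 root stress replicate 3, 1582 without replicate 4, 1169 with only the 8 arrays of the comparison (82.5% of them upwards) and 5967 with array weights. With slide as a fixed block 2392 probes passed, and on slide 3, with 1 array of each group, 94.6% of 1866 probes called elsewhere moved the same way.

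In the root of B71 4856 probes changed, 2466 upwards and 2390 downwards, 1738 of them at least 2-fold. CUST_8014_PI423492394 (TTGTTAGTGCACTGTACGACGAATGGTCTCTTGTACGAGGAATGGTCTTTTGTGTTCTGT) rose by 6.54 ± 0.33 (SE, limma adjusted p = 7.5e-13) to -0.78 ± 0.12 (SD, n = 4), with 1 control array above background, and by 4.30 in the root of B59. CUST_31850_PI423492394 was not well above background in any control array and at least 28.9-fold higher under stress. CUST_3481_PI423492394 (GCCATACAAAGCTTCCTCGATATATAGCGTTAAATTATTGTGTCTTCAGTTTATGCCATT) changed by -6.00 ± 0.59 (SE), from 0.37 ± 0.57 to -5.63 ± 1.17 (SD, n = 4). CUST_14293_PI423492394 changed by -5.76 ± 0.55 (SE), with 1 stressed array above background against 3 for CUST_3481_PI423492394. Both of these also fell in the other combinations of line and tissue, with log2 fold changes of -1.72 to -2.32. On slide 1, with 1 array of each group, 95.5% of 3537 probes called elsewhere moved the same way. With slide as a fixed block 3977 probes passed, and with array weights 8332.

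**Figure D2:**
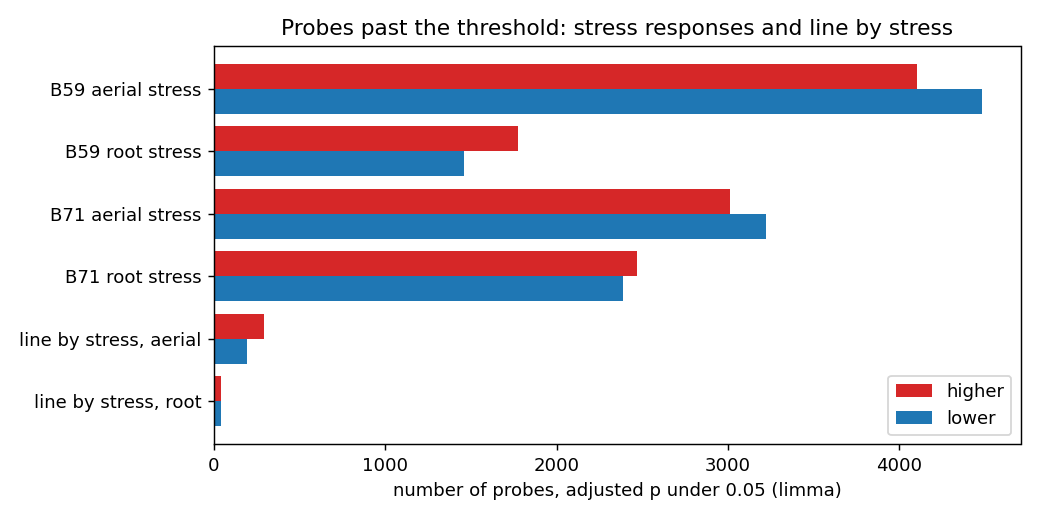
Number of probes past the threshold (limma, adjusted p under 0.05), higher in red and lower in blue, for the stress response of each line and tissue and for the difference of that response between lines. B59 aerial stress has the longest bars (4100 and 4482), and line by stress in the root the shortest (43 and 41).

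Which direction held more calls depended on the scaling of the arrays. After quantile normalization 4781 probes rose and 4009 fell in B59 aerial stress, 3671 rose and 3146 fell in B71 aerial stress, and 2636 rose and 2929 fell in B71 root stress. With the array median as the reference 1445 rose and 1719 fell in B59 root stress.

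The responses of the lines overlapped. In the aerial part 4327 probes passed in both lines in the same direction, against 930 expected of independent lists, and 55 passed in opposite directions. In the root 1855 passed in the same direction, against 273 expected, and 11 in opposite directions. Across all 28792 probes, which are not independent replicates, the fold changes of the lines had Pearson's r = 0.64 and Spearman's rho = 0.63 in the aerial part and 0.62 and 0.57 in the root. The lines share no arrays. Between the tissues of 1 line Pearson's r was 0.40 in B59 and 0.33 in B71. In all 4 comparisons 467 probes rose and 242 fell, where independent lists would give 2.26 and 2.11. The root overlap was 1030 without B59 root stress replicate 3 and 1035 without replicate 4.

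**Figure D3:**
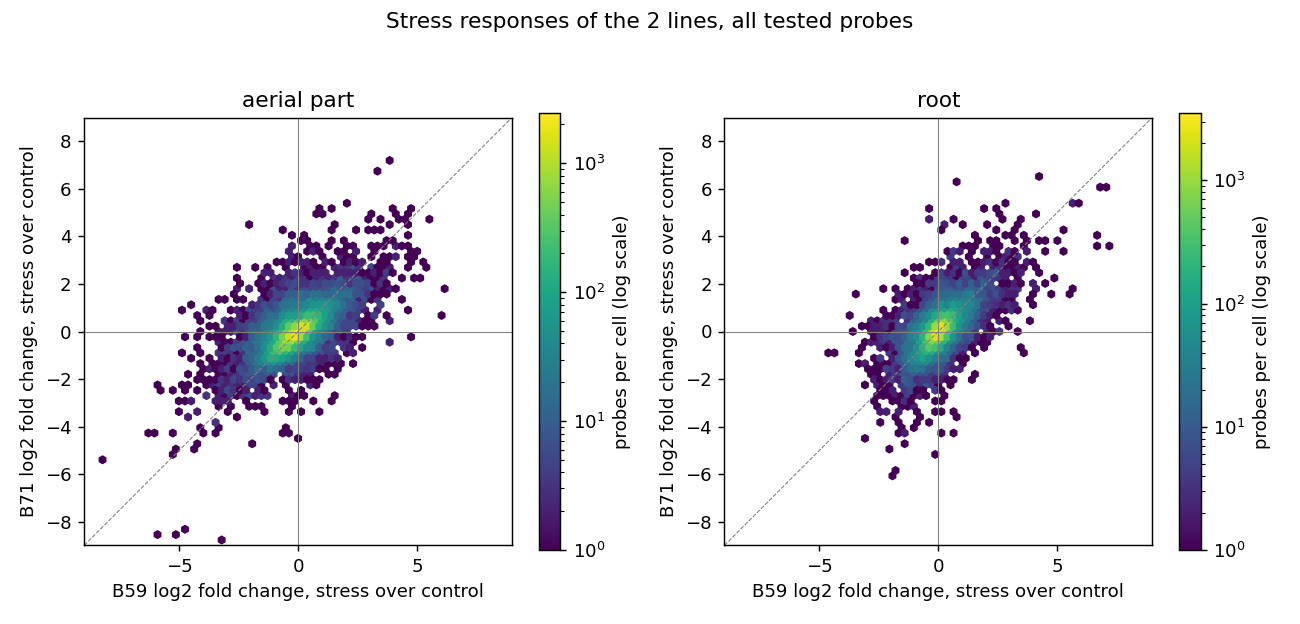
Log2 fold change under stress in B59 (x axis) against B71 (y axis) for all tested probes, in the aerial part (left) and the root (right). Colour gives the number of probes per hexagonal cell on a log scale, and the dashed line marks equal change. The cloud follows the diagonal in both panels, with Pearson's r of 0.64 and 0.62 across probes.

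After removal of the error variance, the SD of the aerial response across probes was 0.657 ± 0.0531 (jackknife SE) in B59 and 0.572 ± 0.0532 in B71, a ratio of 1.15 ± 0.141. In the root it was 0.483 ± 0.107 in B59 and 0.545 ± 0.0468 in B71, a ratio of 0.886 ± 0.210. Neither ratio differed from 1 by more than 2 jackknife errors. The larger count of B59 in the aerial part and of B71 in the root therefore does not show a difference in overall response size. With only the compared groups in each fit the aerial order reversed, at 4916 in B59 and 6592 in B71. Corrected for error variance like the SD, the correlation between lines was 0.834 ± 0.119 in the aerial part and 0.812 ± 0.0732 in the root.

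The difference of the responses was tested directly. In the aerial part 484 probes differed, with B71 minus B59 positive for 291 and negative for 193. Of these, 244 were called under stress in B59 alone, 119 in B71 alone, 66 in both in the same direction and 55 in both in opposite directions. CUST_11817_PI423492394 (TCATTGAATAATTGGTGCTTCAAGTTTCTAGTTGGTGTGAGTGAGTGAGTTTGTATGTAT) rose from -4.30 ± 0.63 to 0.45 ± 0.32 in B59 (SD, n = 4), while its fold change in B71 was -0.23 and did not pass, a difference of -4.98 ± 0.58 (SE, limma adjusted p = 1.56e-05). CUST_14393_PI423492394 differed by -5.23 ± 1.01 (SE). CUST_35081_PI423492394 had a difference of 5.84 ± 1.02 (SE) and CUST_35886_PI423492394 of 4.98 ± 1.09 (SE), both with wide spread in the B59 controls (SD 2.33 for each, n = 4). The aerial count was 304 with only the 16 arrays concerned, 381 with slide as a fixed block, 941 with scan day as a block and 1014 with array weights. It was 309 without B59 aerial control replicate 2, 315 without B71 aerial control replicate 4 and 314 without B71 aerial stress replicate 3. After normexp correction followed by quantile normalization 50.1% of the calls were positive, against 60.1%. With only the 16 arrays concerned 148 were positive and 156 negative.

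In the root 84 probes differed between the lines in their response, 43 positive and 41 negative. CUST_4529_PI423492394 (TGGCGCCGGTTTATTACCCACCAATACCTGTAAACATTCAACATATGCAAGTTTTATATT) rose in B71 from -5.23 ± 0.53 to -1.45 ± 1.28 (SD, n = 4) and was not well above background on any B59 root array, with a fitted difference of 5.21 ± 0.65 (SE, limma adjusted p = 6.75e-05). For CUST_31850_PI423492394 the fitted difference was 5.41 ± 0.73 (SE). Since no B59 root array was above background for the first and no B71 control root array for the second, these values are not exact folds. CUST_34643_PI423492394 had a fitted difference of -5.04 ± 1.05 (SE), which is not an exact fold either, since no B71 stressed root array was above background. CUST_6382_PI423492394 had -4.38 ± 0.95 (SE). Neither of these last probes passed with slide as a fixed block, where the fitted differences were -5.17 for CUST_34643_PI423492394 and -5.19 for CUST_6382_PI423492394. Both passed with slide as a random block. After normexp correction followed by quantile normalization the difference of CUST_34643_PI423492394 was -1.55 and did not pass (limma adjusted p = 0.109). Without single arrays the limma adjusted p of CUST_34643_PI423492394 was 0.0546 to 0.0680 where it missed the threshold, which was without B59 root control replicate 1, B59 root stress replicates 1 and 3, B71 root control replicates 1 and 2, or B71 root stress replicates 1 and 4. For CUST_6382_PI423492394 it was 0.0514 to 0.105, without B59 root control replicates 1 and 4, any B59 root stress array, B71 root control replicates 1 and 4, or B71 root stress replicates 1 and 4. The root count was 30 with slide as a fixed block and 104 with slide as a random block, 52 without a filter, 156 after quantile normalization, 199 after normexp correction followed by quantile normalization, 162 in the deposited table, 160 with scan day as a block and 439 with array weights. It was 200 without B59 root control replicate 2, 45 without B71 root stress replicate 1 and 54 without replicate 4. With the array median as the reference 63.5% of the calls were positive, and with scan day as a block 43.1%, against 51.2%.

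B71 and B59 differed in 10498 probes in control aerial parts (5010 higher in B71), 11672 in control roots (5516 higher), 9615 in stressed aerial parts (4760 higher) and 10959 in stressed roots (5040 higher). These are differences in signal. A sequence difference between the lines under a probe can give them as well as a difference in expression, and the 2 cannot be told apart here. CUST_9717_PI423492394 (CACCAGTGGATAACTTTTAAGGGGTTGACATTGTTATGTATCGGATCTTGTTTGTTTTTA) was well above background on all 16 arrays of B71 and none of B59, and was at least 986-fold higher in B71 control roots (limma adjusted p = 2.48e-19). CUST_7765_PI423492394 (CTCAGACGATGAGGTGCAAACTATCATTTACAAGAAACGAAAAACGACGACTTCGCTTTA) showed the opposite, at least 628-fold higher in B59 control roots (limma adjusted p = 6.68e-24). In control aerial parts CUST_10021_PI423492394 was at least 2523-fold higher in B71 and CUST_29509_PI423492394 at least 1077-fold higher in B59. Elsewhere these 2 probes varied widely in the dimmer line. CUST_10021_PI423492394 was at -3.45 ± 3.84 in B59 control roots, with 3 arrays above background. CUST_29509_PI423492394 was at -6.84 ± 4.38 in B71 stressed aerial parts, with 1 (SD, n = 4). In all 4 settings of tissue and treatment 5882 probes differed in 1 direction, 3239 higher in B71 and 2643 higher in B59, and 2026 of them differed at least 4-fold in each setting. Between the aerial part and the root of controls, which share no arrays, the line differences had Pearson's r = 0.87 across probes. On the slides that held an array of each line, 89.5% to 98.9% of the probes called from the other arrays had the same sign.

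Probes that were aerial-preferred in the controls of the other line were examined under stress. In the aerial part of B59 1632 of 4295 such probes fell, 387 rose and 2276 were not called. Of the other probes 11.6% fell and 15.2% rose. In that of B71 1677 of 4297 fell, 185 rose and 2435 were not called, while 6.30% of the other probes fell. The mean score of the set differed by -0.31 in B59, from 1.22 ± 0.18 to 0.91 ± 0.03 (SD, n = 4, exact two-sided permutation p = 0.0286), and by -0.46 in B71, from 1.17 ± 0.09 to 0.71 ± 0.14 (SD, n = 4, exact two-sided permutation p = 0.0286). That p is the smallest that 4 against 4 arrays allow. After adjustment over the 8 scores tested, both were 0.0762 and did not pass. A score could have passed only if most of the 8 had reached that smallest p. Not passing therefore does not argue against a fall. Of 3837 root-preferred probes 1070 rose, 154 fell and 2613 were not called in the aerial part of B71, and their score differed by 0.41, which did not pass either (exact two-sided permutation p = 0.0286, 0.0762 adjusted). There 7.77% of the other probes rose and 12.3% fell. In the aerial part of B59 1095 of 4062 root-preferred probes rose (27.0%) and 562 fell (13.8%), with an exact two-sided permutation p = 0.371 for the score. Of the other probes 12.2% rose and 15.9% fell. No score passed adjustment in the root either. Root-preferred probes had score differences there of 0.12 in B59 and 0.09 in B71 (exact two-sided permutation p = 0.0571 in each, 0.0914 adjusted), and aerial-preferred probes of -0.08 and -0.07 (exact two-sided permutation p = 0.286 and 0.429, 0.381 and 0.429 adjusted).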

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

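The tests of 1 deviating array, of dimmer arrays, of sequence differences, of mixed tissue and of GC content, and the difference between tissues in line by stress, were chosen only after related results had been seen.

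Of 116 groups of 4 arrays examined for a value far from the others, 7 stood apart, where chance gives about 5.8. B59 aerial control replicate 3 had a mean correlation of 0.964 with the other arrays of its group, against 0.976 to 0.978 for those. It also had the lowest 75th percentile signal, 517. Leaving it out gave 8618 probes for B59 aerial stress against 8582, and 375 for line by stress in the aerial part (199 positive and 176 negative) against 484 (291 and 193). Single-probe values stood apart for CUST_7570_PI423492394 in B59 root control replicate 1 (-6.18, others -9.13 to -8.68), for CUST_6910_PI423492394 and CUST_8301_PI423492394 in B71 aerial stress replicate 3 (-2.39 and -5.03), and for CUST_29509_PI423492394 in B59 aerial control replicate 2 (3.68, others 3.83 to 3.85). CUST_7765_PI423492394 stood apart in B59 root control replicate 2 (2.34, others 2.55 to 2.58) and in B71 root stress replicate 1 (-8.64, others -7.93 to -7.85).

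The lines differed in their stress response at 484 probes in the aerial part and 84 in the root. Named probes with a line-by-stress difference past the threshold in the aerial part were CUST_12826_PI423492394 (-4.39), CUST_14393_PI423492394 (-5.23), CUST_11817_PI423492394 (-4.98), CUST_14252_PI423492394 (3.47), CUST_14251_PI423492394 (3.60), CUST_35081_PI423492394 (5.84) and CUST_35886_PI423492394 (4.98). In the root these were CUST_27512_PI423492394 (-3.48), CUST_8014_PI423492394 (2.24), CUST_31850_PI423492394 (5.41), CUST_3481_PI423492394 (-4.09), CUST_14293_PI423492394 (-3.86), CUST_4529_PI423492394 (5.21), CUST_34643_PI423492394 (-5.04) and CUST_6382_PI423492394 (-4.38). For CUST_14252_PI423492394, CUST_31850_PI423492394, CUST_4529_PI423492394 and CUST_34643_PI423492394 at least 1 of the groups compared had no array well above background, so these fitted differences are not exact. CUST_3481_PI423492394 and CUST_14293_PI423492394 overlap in sequence and may measure the same transcript.

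More probes differed by line and stress in the aerial part than in the root. The tables argue against a single array as the whole cause, narrowly, since the lowest aerial count without 1 array was 309 and the highest root count 200, against a bound of 1.5 times. With slide as a fixed block 381 aerial and 30 root probes passed. This argues against differences between slides as the whole cause of the larger aerial count. A comparison of counts is no test of a tissue difference, and the direct test weakened under that block. The tissue difference itself passed at 42 probes, at 5 with slide as a fixed block and at 73 without B59 aerial control replicate 1, so which probes respond differently by tissue stays mostly open. A biological difference between the tissues remains untested beyond these counts.

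Well above background on all 16 arrays of B71 and none of B59 were 393 probes, and 44 showed the opposite. Their median difference before scaling was 5.47 (log2), beyond the 2.44 between the dimmest and the brightest array, which argues against array brightness as the whole cause of these differences. Whether brightness contributes to the 393 against 44 was not tested. On all 16 arrays of the line, 22589 probes were well above background in B59 and 23832 in B71. Among probes at least 4-fold different in all 4 settings, 1362 were higher in B71 and 664 in B59. The line difference passed the threshold in all 4 settings for 100% of the 437 probes, which the way they were chosen nearly fixes. A sequence difference under the probe and a difference in expression would both give that, so they cannot be told apart without the genomes of the lines.

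In the aerial part 1632 of 4295 aerial-preferred probes fell under stress in B59 and 1677 of 4297 in B71. The scores of these sets did not pass (adjusted exact permutation p = 0.0762 in each), which the small number of arrays nearly fixed. If root tissue had been mixed in, the share needed for the fall would be 24.7% in B59 and 28.3% in B71, and probes at least 16-fold higher in root would have risen by a median of 2.70 and 3.86 (log2). Their medians were -0.17 and 0.52, with jackknife errors of 0.222 and 0.219 on their distance to the bound, which argues against mixed tissue as the whole cause. After a linear trend on probe GC content was removed from each array the score differences were -0.32 in B59 and -0.46 in B71, against -0.31 and -0.46 before. A lower level of aerial-type transcripts under stress remains a hypothesis.

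Other splits of the same arrays gave fewer probes than the real one in the stress, line and tissue comparisons. This argues against chance for these but does not exclude it, since 1 of 35 is the smallest share that 35 splits allow. Nor can splits tell whether the arrays of a group are technical repeats. For the stress responses, 1 of 35 splits, the real one, gave as many probes in each case, with 8582 against a highest other of 2555 in the aerial part of B59, 3235 against 458 in its root, 6229 against 428 in the aerial part of B71 and 4856 against 50 in its root. The line differences gave 1 of 35 each, with 10498 against 3442 in control aerial parts, 11672 against 490 in control roots, 9615 against 1692 in stressed aerial parts and 10959 against 75 in stressed roots. For the tissue difference 1 of 100 drawn splits did, with 19230 against 15639, a split that moved 2 arrays. For line by stress, 4 of 100 splits gave at least 484 in the aerial part (highest other 5657), and 5 of 100 gave at least 84 in the root (highest other 2145). The highest of these moved 8 arrays of B71 and 2 of B59 in the aerial part, and 6 arrays of B71 in the root. Exchanging the treatments of 1 line turns the stress response that the lines share into a difference, so such splits are no fair picture of chance. Which arrays the other splits that reached the real count moved was not recorded. Whether chance explains either line-by-stress count is therefore left open.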

How the results depend on the processing

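Of 154 counts under 14 alternatives, 139 stayed within 1.5 times the reported count. No named probe reversed in 664 settings, which the choice of these probes by their large changes nearly fixes. In 21 of these settings a named probe lost the threshold, all of them CUST_34643_PI423492394 or CUST_6382_PI423492394 in the root line-by-stress comparison. Alternatives for the overlap beyond its p threshold, for the tissue-preferred sets and for the difference between tissues in line by stress were added after seeing the data. The gene-list alternatives could not be run, since no probe had a gene. Signal over background limits dim probes, for which folds between a pair of groups are given as bounds only where no array of the dimmer group was well above background. Where only some of its arrays were, the fitted fold is given and is imprecise, and line-by-stress differences of dim probes are not exact. The causes of the changes below were not tested.

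With only the compared groups in the fit, the counts were 4916 for B59 aerial stress, 1169 for B59 root stress and 304 for aerial line by stress. In that setting B71 aerial stress had 6592 and B71 root stress 5892, so in the aerial part B71 then had more calls than B59. Array weights gave 5967 for B59 root stress, 10805 for B71 aerial stress, 8332 for B71 root stress, 1014 for aerial and 439 for root line by stress. Scan day as a block gave 941 aerial and 160 root line-by-stress probes. Root line by stress was 156 after quantile normalization, 199 after normexp correction followed by quantile normalization, 162 in the deposited table, 52 without a filter and 30 with slide as a fixed block. The tissue-by-line-by-stress count was 42, and 5 with slide as a fixed block. With arrays left out in turn, counts ranged from 1534 to 3752 for B59 root stress, from 309 to 708 for aerial and 45 to 200 for root line by stress, and from 1030 to 2160 for the root overlap. The tissue-by-line-by-stress count ranged from 31 to 73, the line differences from 9548 to 10402 in control aerial parts, 10158 to 11747 in control roots, 8710 to 9534 in stressed aerial parts and 9850 to 10540 in stressed roots, and the tissue difference from 18723 to 19552. The lowest and highest for the remaining counts were 7435 to 8618 (B59 aerial stress), 5143 to 5783 (B71 aerial stress), 3631 to 4429 (B71 root stress) and 3732 to 4741 (aerial overlap).

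No sign was seen that the replicate number pairs stress with control arrays, but the check cannot exclude a weak pairing. Pairing of aerial part and root by number was not checked on its own. Deviations of same-numbered arrays of stress and control correlated between -0.357 and 0.351, and 3 of 16 arrays correlated best with their own number. With the replicate block the counts were 8507, 3216, 6156 and 4781 for stress in B59 aerial part, B59 root, B71 aerial part and B71 root. Under the same block line by stress gave 463 aerial and 81 root probes, the line differences 10490, 11629, 9566 and 10899, and the tissue difference 19239. The block ended the call of CUST_6382_PI423492394 (adjusted p = 0.0651) and changed no other call of a named probe.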

Other observations

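Values in the next paragraph were examined after the data had been seen, and the test of B71 controls against stressed B59 was chosen before its result.

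In both lines 998 probes rose in the aerial part without a call in either root, and 1560 fell. In both lines 329 rose and 294 fell in the root without a call in either aerial part. A call missing in 1 tissue does not show a difference between tissues, which was not tested here. The B59 root stress arrays lay apart on PC3, at 0.93 and -1.46 for replicates 1 and 2 and at -41.1 and -43.1 for replicates 3 and 4, and leaving out either of the last pair lowered the count of that comparison to 1534 and 1582. Of the 484 aerial line-by-stress probes 50.4% also differed between the lines in control roots, which share no arrays with them, against 40.5% of all tested probes. Of the 84 root probes 45.2% differed between the lines in control aerial parts, against 36.5%.

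A hypothesis was that unstressed B71 resembles stressed B59. Across probes, the slope of the line difference in controls on the stress response of B59, with the B59 controls split so that no array was shared, was 0.0847 ± 0.179 (jackknife SE) in the aerial part and 0.0946 ± 0.368 in the root. Neither lies beyond its error, so the hypothesis stays open. With shared controls the slopes were 0.251 and 0.290, but sharing by itself pushes such a slope upwards.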
